A study of Aspergillus niger with 6 samples.

How the data were processed

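Transcript levels were measured by RNA sequencing in 6 libraries of Aspergillus niger strain H915-1, a filamentous fungus grown as pellets in a citrate fermentation. Groups were taken from the age and aeration given in the labels. They were 6, 12, 24, 36 and 48 h at an air supply of 3 vvm, and 48 h at 1.5 vvm, where vvm is the volume of air per volume of culture per minute. Each group had 1 library. Per the labels' protocols, pellets were frozen in liquid nitrogen, RNA was purified on a silica column kit, and libraries were made with the Illumina TruSeq RNA kit. That kit in its usual form does not mark strand, and whether counting used strand is not given in the sources used here.

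The deposited FPKM values (fragments scaled by transcript length and by mapped fragments) are the authors' own, in 2 tables per the file headers. The submitters' processing notes name TopHat2 2.0.9 and Cufflinks 2.1.1. The genome build and the gene annotation are not given in the sources used here. The time course table listed 9953 genes with the 5 libraries at 3 vvm. The other table listed 10234 genes with the 1.5 vvm library and the 24 h library at 3 vvm, and it did not hold the 48 h library at 3 vvm. The 24 h FPKM was identical in both tables at 9930 of the 9930 loci they share. No scaling across the libraries of a table was therefore visible in FPKM, and the 2 tables were merged by locus. Neither table listed a gene at 0 in each of its libraries. As a result, 304 genes were listed only beside the 1.5 vvm library and 23 only in the time course table. The second table held 4 further value columns that matched no label, and they were not used.

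The columns headed as counts are a deposited signal, not raw counts: the authors scaled them so that the libraries of a table share 1 total. Dividing each column by its smallest step gave whole fragments, within 0.1 of a whole number, for at least 99.9% of the values in each library. Recovered totals were 5062817 fragments at 6 h, 5199184 at 12 h, 5298533 at 24 h, 5371485 at 36 h, 6100480 at 48 h, and 6708034 at 1.5 vvm. Counting error alone gives a relative SD of 31.6% at 10 fragments and of 3.16% at 1000 fragments. A count of 0 allows up to 3 fragments, which for the median gene was 0.524 FPKM at 6 h and 0.415 FPKM at 1.5 vvm. Intervals and floors cover counting error only, since fragments without molecular identifiers are not independent molecules.

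Log2 changes were computed as log2(FPKM + 1), with genes kept at 1 FPKM or more in at least 1 library of a comparison, and genes at least 2-fold apart were counted. This scale understates the change of low genes. With 1 library per group there is no replicate check of any difference between 2 libraries, and no p-value was computed for them. The comparisons were 12, 24, 36 and 48 h with 6 h at 3 vvm, each time with the one before it, and 1.5 with 3 vvm at 48 h. The last comparison sets FPKM from one table against FPKM from the other. Genes with a 4-fold range over the 5 times were sorted by the time of their highest value. Intervals of fragment ratios and of shares are exact 95% binomial intervals (Clopper-Pearson).

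Gene identifiers matched 0 of the 14404 genes in the table of names given for assembly ASM285v2, so gene names could not be used, and 40 gene lists fixed before the data were examined could not be applied. The rule for named genes, also fixed before the data were examined, then allowed 2 identifiers higher and 2 lower in each of the 48 h with 6 h and the 1.5 with 3 vvm comparisons. They are those with the largest log2 change among genes of at least 10 FPKM in the higher library. Regions took the place of named genes. A run was at least 5 consecutive genes past the filter on one contig, each at least 2-fold apart in the same direction, and runs of at least 7 genes were named. This rule was set after the data were seen. The correlation of log2 change between neighbouring genes and the number of runs were compared with 1000 shuffles of gene order within contigs. Coordinates are those of the authors' contigs, with the start raised by 1 so that positions count from 1. Of the spans, 46.9% were multiples of 3, so they include introns or untranslated parts. No listed span overlapped the next. A total of 10238 genes lay on 8 long contigs of at least 100 genes, out of 20 contigs.

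As an alternative added after the data were seen, edgeR 4.0.16 in R 4.3.3 was run on the recovered fragments with its quasi-likelihood test and TMM normalization. One model fitted log2 time over the 5 libraries at 3 vvm, and another fitted log2 time and aeration over all 6 libraries, where the aeration term fits 1 library exactly. Their spread is the deviation of libraries from the fitted line, with 3 residual degrees of freedom, and not a spread between replicates. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05, over genes with at least 15 fragments in total.

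Both steps were tested on simulated data. With fragments drawn by Poisson from the means and depths of the 48 h and 6 h libraries at 3 vvm, fold counting recovered 99.5% of 200 genes changed 3-fold (of 8946 genes) and 100% of 200 changed 4-fold (of 8967 genes), while 135 of 8953 unchanged genes passed 2-fold. In the comparison of aeration rates, 98.5% of 200 genes changed 3-fold were recovered, and 108 of 9590 unchanged genes passed 2-fold. In both comparisons the changed genes were drawn only from genes with a mean of at least 10 FPKM. Recovery of lower genes was not tested. For the trend over 8858 genes, 191 of 200 genes with a slope of 1 (log2 per doubling of time) were called. There were 10 false calls. Slopes under 1 were not simulated, while genes called in the data had median slopes of 0.656 (rising) and -0.492 (falling). Other pseudocounts (0.1 and 5 FPKM), filters (none and 10 FPKM), scalings (a common sum, median ratio) and thresholds (1.5-fold and 4-fold) were tried. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for all other steps.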

Results

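Gene expression was followed through a citrate fermentation of Aspergillus niger H915-1. Libraries came from 5 times at an air supply of 3 vvm and from 48 h at 1.5 vvm, with 1 library per group. Total fragments per library lay between 5062817 (6 h) and 6708034 (1.5 vvm). The 10 most abundant genes took 19.9% of the fragments at 6 h, 18.9% at 48 h and 14.7% at 1.5 vvm. Across genes, the Pearson correlation of log2(FPKM + 1) was highest between 36 and 48 h (0.973) and lowest between 6 and 48 h (0.838). The 1.5 vvm library correlated at 0.926 with 24 h, 0.922 with 36 h and 0.923 with 48 h at 3 vvm. Genes are not independent replicates, and 15 pairs of libraries were compared. No difference between 2 libraries given here has a replicate check.

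The first comparison asked how expression differed between the start of the sampled course and later times at 3 vvm. At 12 h, 681 genes were at least 2-fold higher and 631 were at least 2-fold lower than at 6 h, of 8886 genes. At 24 h the counts were 1050 higher and 858 lower, at 36 h 1570 and 1031, and at 48 h 1577 and 1083 of 9036 genes. Between consecutive times, 479 genes were higher and 375 lower at 24 h relative to 12 h, 497 and 276 at 36 h relative to 24 h, and 245 and 179 at 48 h relative to 36 h. At 48 h, 558 genes were at least 4-fold higher than at 6 h and 267 at least 4-fold lower, and 106 and 53 genes differed by at least 16-fold. Counting error alone would place about 135 genes past 2-fold in the 48 h comparison. With values rescaled to a common sum, the share of higher genes among those past 2-fold was 62.3% at 12 h in place of 51.9%, and 66.0% at 24 h in place of 55.03%, with the median of all genes at 24 h at a log2 change of 0.19 in place of 0.03.

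**Figure D1:**
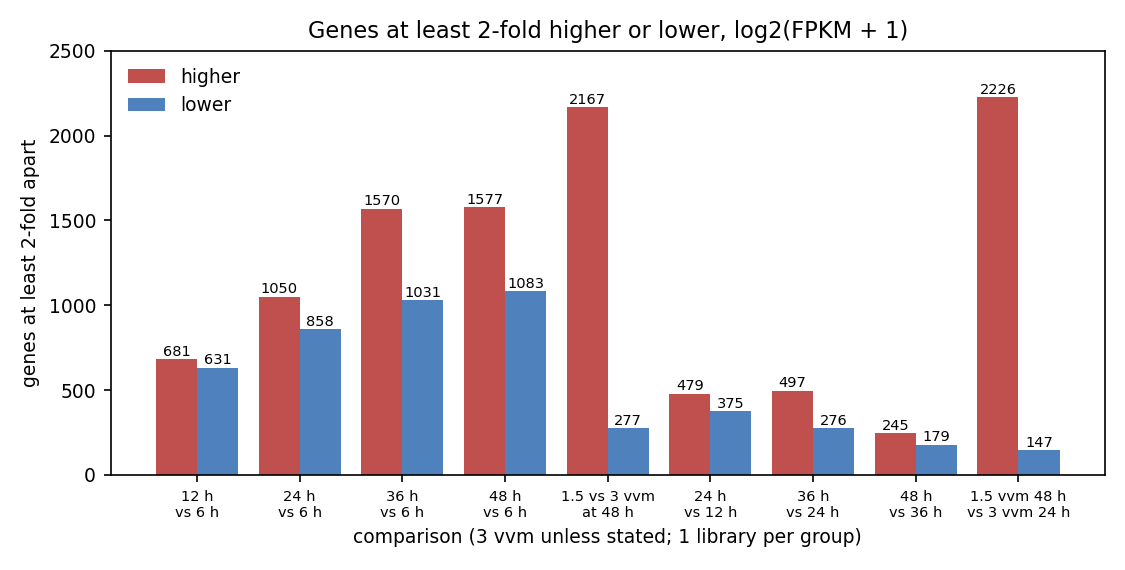
Bars give the number of genes at least 2-fold higher (red) or lower (blue) on the log2(FPKM + 1) scale in each comparison named on the x axis, from 1 library per group. Counts against 6 h went from 681 and 631 genes at 12 h to 1577 and 1083 at 48 h, and the comparison of 1.5 with 3 vvm had 2167 higher and 277 lower.

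The rule for named genes gave 2 lower and 2 higher genes in the 48 h comparison. The gene evm.model.unitig_6.59 (contig unitig_6, 212425 to 213654) was at 7968 FPKM at 6 h, 33.4 at 12 h and 6.44 at 48 h, or 33490 and 32 fragments at 6 and 48 h. Relative to depth, that was 1261-fold lower (95% counting interval 893 to 1844). The gene evm.model.unitig_5.1067 (unitig_5, 3473625 to 3474527) was at 2240 FPKM at 6 h and 11.8 at 48 h, 188-fold lower (140 to 259). In the other direction, the gene on contig 1 from 4189517 to 4191007 was at 10.01 FPKM at 6 h, 514 at 12 h, 3000 at 24 h and 2832 at 48 h, which was 283-fold higher at 48 h (221 to 369). The gene evm.model.unitig_2.1242 (unitig_2, 4146864 to 4147336) had 0 fragments at 6 and 12 h, 157 at 24 h, 21 at 36 h and 278 at 48 h. At 48 h it was at least 62.1-fold higher by the lower 95% counting limit, and 76.9-fold above the 3 fragments that a count of 0 allows at 6 h. The files do not pair these identifiers with gene names or functions.

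Genes next to each other on a contig tended to differ alike between 48 and 6 h. The correlation of log2 change between neighbours was 0.22 over 9017 pairs, and the highest value in 1000 shuffles of gene order was 0.04. There were 23 runs of at least 5 consecutive genes at least 2-fold apart in one direction, 17 higher and 6 lower, where shuffled orders gave 1.49 on average and at most 6. Of the 7 runs with at least 7 genes, 5 were higher at 48 h and 2 were lower. Of the 1000 shuffled orders, 40 held a run of at least 7 genes, at most 1 each, and the longest had 9 genes.

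The medians of both long lower runs were highest at 6 h, and single members differed from them. The run on unitig_1 from 4759122 to 4799319 held 11 genes, and their median was 166 FPKM at 6 h, 32.2 at 12 h, 12.8 at 24 h and 6.62 at 48 h. The log2 changes of these 11 genes at 48 h lay between -7.25 and -1.11, with a median of -4.46. At 6 h 1 of them was under 10 FPKM, with 5 fragments, and 10 were highest at 6 h among the 5 times. The run on contig 1 from 3043016 to 3062650 held 10 genes with a median of 361 FPKM at 6 h, 32.4 at 12 h and 15.7 at 48 h, and a median log2 change of -3.82. At 6 h 2 of these genes were under 10 FPKM, with 1 and 31 fragments, and 8 of the 10 were highest at 6 h.

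The higher runs reached their level at different times. The run of 7 genes on contig 1 from 4269213 to 4295529 had a median of 1.25 FPKM at 6 h, 273 at 12 h and 243 at 48 h, with a median log2 change of 4.94. The 8 genes on contig 1 from 4186899 to 4206859, among them the gene from 4189517, had a median of 6.78 FPKM at 6 h, 52.4 at 12 h and 94.6 at 48 h. The 7 genes on unitig_2 from 4205855 to 4227129 stood at 21.7 FPKM at 6 h, 40.3 at 12 h, 24.3 at 24 h, 67.5 at 36 h and 58.2 at 48 h. On contig 1 from 1814238 to 1832058, the median of 7 genes was 14.8 FPKM at 6 h, 57.6 at 12 h, 44.0 at 24 h, 93.8 at 36 h and 73.6 at 48 h. The 7 genes on unitig_3 from 784015 to 800671 had a median of 0.505 FPKM at 6 h, 5.41 at 12 h, 1.83 at 24 h, 8.01 at 36 h and 16.7 at 48 h. The gene with the fewest fragments at 48 h had 100 in the run from 1814238 and 7 or 8 in the other 4 higher runs.

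**Figure D2:**
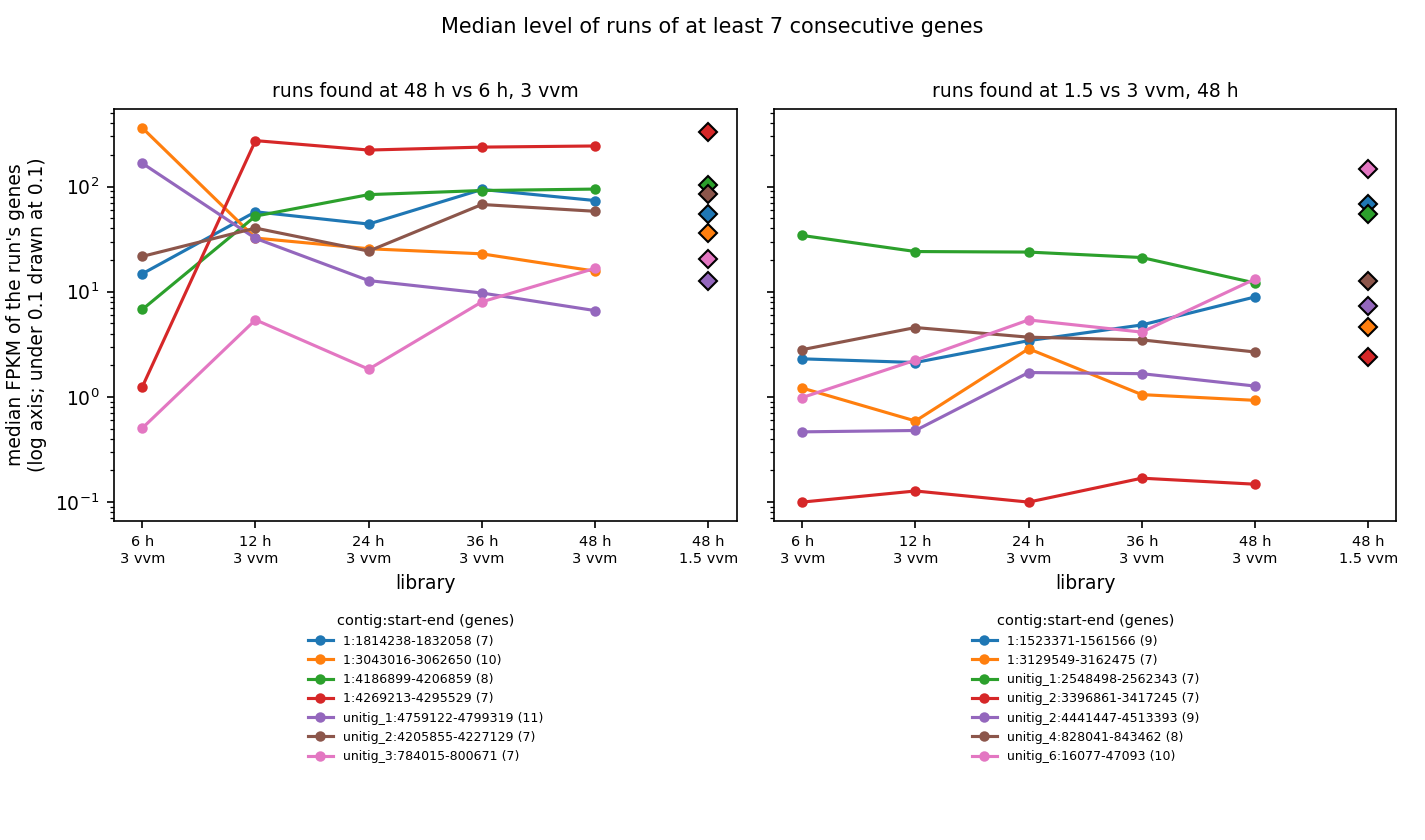
Each line gives the median FPKM (log axis) of the genes of 1 run of at least 7 consecutive genes in the 5 libraries at 3 vvm, and the diamond of the same colour gives it at 1.5 vvm (over 9 of 10 genes for the run on contig 1 from 3043016). The left panel has the runs of the 48 h and 6 h comparison and the right panel those of the 1.5 and 3 vvm comparison, where the run on unitig_6 went from 13.2 to 148 FPKM.

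Genes near the ends of contigs were past 2-fold more often than other genes in the 48 h comparison. Of 326 genes within 100 kb of the first base or the last gene of a long contig, 27.9% were lower at 48 h (95% interval 23.1 to 33.1), against 11.4% of 8693 genes elsewhere (10.7 to 12.1). The shares of higher genes were 24.2% near ends (19.7 to 29.3) and 17.2% elsewhere (16.4 to 18.0). Among genes of at least 10 FPKM in the higher library, 26.4% near ends and 11.3% elsewhere were lower. Neighbouring genes are not independent, so these intervals are too narrow. Genes near ends had a lower level, with a median of 9.98 FPKM in the higher library against 37.8 elsewhere. Among all genes of 1 to 10 FPKM, 384 of 2010 were higher and 265 lower at 48 h. The shares were not matched on level. Whether contig ends are chromosome ends is not given in the sources used here.

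The second comparison asked at which time genes were highest. Of 9189 genes, 1223 had at least a 4-fold range over the 5 times. Of these, 349 were highest at 6 h and 393 at 48 h, while 89 were highest at 12 h, 137 at 24 h and 255 at 36 h. Together, 39.3% were highest at one of the 3 times in between. The genes highest at 6 h had a median of 46.4 FPKM there, 11.2 at 12 h and 5.19 at 48 h. Those highest at 24 h had a median of 7.23 FPKM at 6 h, 50.05 at 24 h and 30.5 at 48 h. Over all 5 times, 206 of the 1223 genes were never lower than at the time before and 91 were never higher. With a pseudocount of 5 FPKM the counts were 188, 48, 80, 144 and 209 genes from 6 to 48 h, and without the 6 h library they were 150, 84, 128 and 231 from 12 to 48 h.

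A trend over the 5 times was tested on the recovered fragments, as an alternative chosen after the data were seen. With edgeR's quasi-likelihood test, 855 genes rose and 854 fell with log2 time at a Benjamini-Hochberg adjusted p below 0.05, of 8858 genes. Of those that rose, 778 were also at least 2-fold higher at 48 h than at 6 h, and of those that fell, 644 were at least 2-fold lower. The counts depended on the time scale and on single libraries. With time in hours in place of log2 time, 258 genes rose and 175 fell. Without the 6 h library 209 genes rose and 106 fell, without 36 h 219 and 168, and without 48 h 302 and 301.

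The third comparison asked how expression at 48 h differed with a lower air supply. Of 9787 genes, 2167 were at least 2-fold higher at 1.5 than at 3 vvm and 277 at least 2-fold lower. At least 4-fold apart were 568 higher and 51 lower. The balance depended on level: among genes of 1 to 10 FPKM 978 were higher and 24 lower, among genes of at least 50 FPKM 424 and 150. FPKM of the 3 vvm library came from the other table. Higher genes made up 88.7% of those past 2-fold as deposited and 78.5% (1701 higher, 465 lower) with values rescaled to a common sum, which set the median of all genes at a log2 change of 0.04 in place of 0.28. Against the 24 h library of its own table, the 1.5 vvm library had 2226 genes higher and 147 lower.

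The 1.5 vvm library also stood apart at the low end of expression. Of the 9953 genes of the time course table, 3.76% (48 h) to 5.03% (24 h) were at 0 in the libraries at 3 vvm. At 1.5 vvm 30 genes (0.301%) were at 0, of which 23 were not listed with that library and were counted as 0. Among the 9930 genes in both tables, 158 were below 1 FPKM at 1.5 vvm, against 1210 at 48 h and 3 vvm. The 442 of them below 0.5 FPKM in each library at 3 vvm had a median of 1.57 FPKM and 13 fragments at 1.5 vvm. With that median taken off the values of the 1.5 vvm library, 1465 genes were higher and 512 lower than at 3 vvm, a step chosen after the data were seen.

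**Figure D3:**
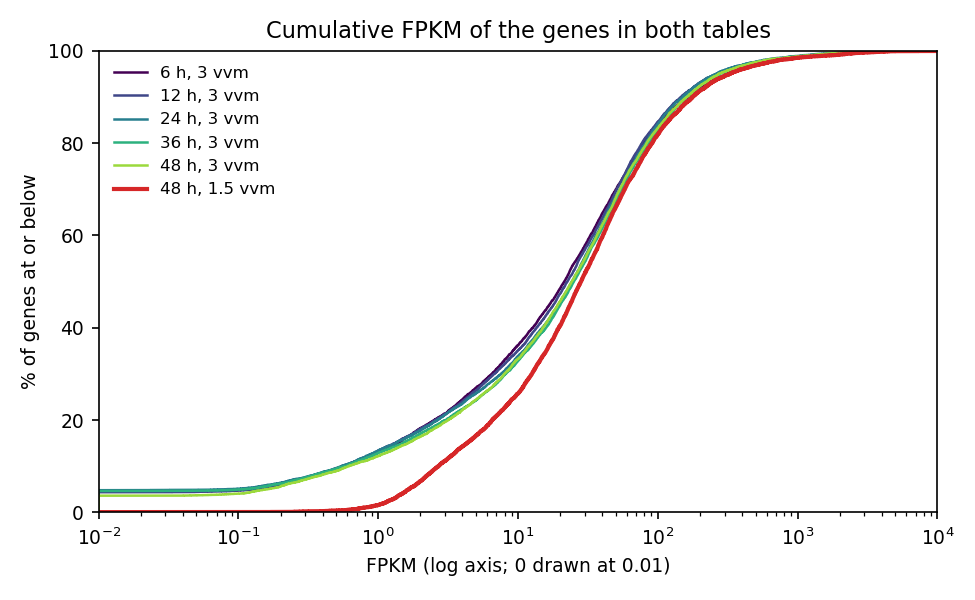
Each curve gives the percentage of the 9930 genes in both tables, without the 23 listed in the time course table alone, at or below the FPKM on the x axis (log axis, with 0 drawn at 0.01) in 1 library. The 5 curves at 3 vvm start between 360 and 478 genes at 0, and the red curve of the 1.5 vvm library starts at 7 genes.

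The largest differences between the aeration rates were in genes with varied courses at 3 vvm. The gene evm.model.unitig_6.59, high at 6 h and at 6.44 FPKM at 48 h and 3 vvm, was at 1473 FPKM at 1.5 vvm, 229-fold higher (162 to 335). The gene evm.model.unitig_3.1094 (unitig_3, 3775815 to 3776108) had 0 fragments at 48 h and 3 vvm and 77 at 1.5 vvm, at least 18.5-fold higher by the lower 95% counting limit and 23.3-fold above the 3 fragments that a count of 0 allows. It had 11 fragments or fewer in each library at 3 vvm. Lower at 1.5 vvm were evm.model.unitig_4.998 (unitig_4, 3485457 to 3487130), at 6.14 in place of 151 FPKM and 24.5-fold lower (19.0 to 32.1), and evm.model.unitig_1.1435 (unitig_1, 4902137 to 4903828), at 28.4 in place of 502 FPKM and 18.7-fold lower (16.5 to 21.3). At 6 h, evm.model.unitig_4.998 had been at 792 FPKM and evm.model.unitig_1.1435 at 144.

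Runs of neighbouring genes were nearly all higher at 1.5 vvm. There were 36 runs of at least 5 genes, 35 higher and 1 lower, where shuffled orders gave 4.32 on average and at most 11. With 2167 genes higher and 277 lower, the gene counts alone would make most runs higher. Shuffled runs were counted over both directions together. Runs of at least 7 genes numbered 7, where 200 of the 1000 shuffled orders held such a run and none more than 3. The longest in shuffled orders had 11 genes, and 6 orders held one of at least 10, the length of the longest real run. The correlation between neighbours was 0.18, and the highest in shuffled orders was 0.03. The run of 10 genes on unitig_6 from 16077 to 47093 had a median of 148 FPKM at 1.5 vvm and 13.2 at 3 vvm, with a median log2 change of 3.27, and it began 16.1 kb from the start of the contig. The run of 9 genes on contig 1 from 1523371 to 1561566 was at 68.8 and 8.92 FPKM. The 7 genes on unitig_1 from 2548498 to 2562343 had a median of 54.6 FPKM at 1.5 vvm and 12.1 at 3 vvm, and of 34.3 at 6 h. The other 4 runs of at least 7 genes had medians of 2.42 to 12.8 FPKM at 1.5 vvm. The gene with the fewest fragments at 1.5 vvm had between 1 and 57 fragments in these 7 runs. With 1.57 FPKM taken off each gene at 1.5 vvm, there were 13 runs, 11 higher and 2 lower, and these were not compared with shuffled orders. Of the genes in the 7 long runs, those still at least 2-fold higher were 8 of 10 on unitig_6, 8 of 9 and 4 of 7 on contig 1 (from 1523371 and from 3129549), and 5 of 7 on unitig_1. On unitig_2 they were 2 of 7 from 3396861 and 7 of 9 from 4441447, and on unitig_4 6 of 8.

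**Figure D4:**
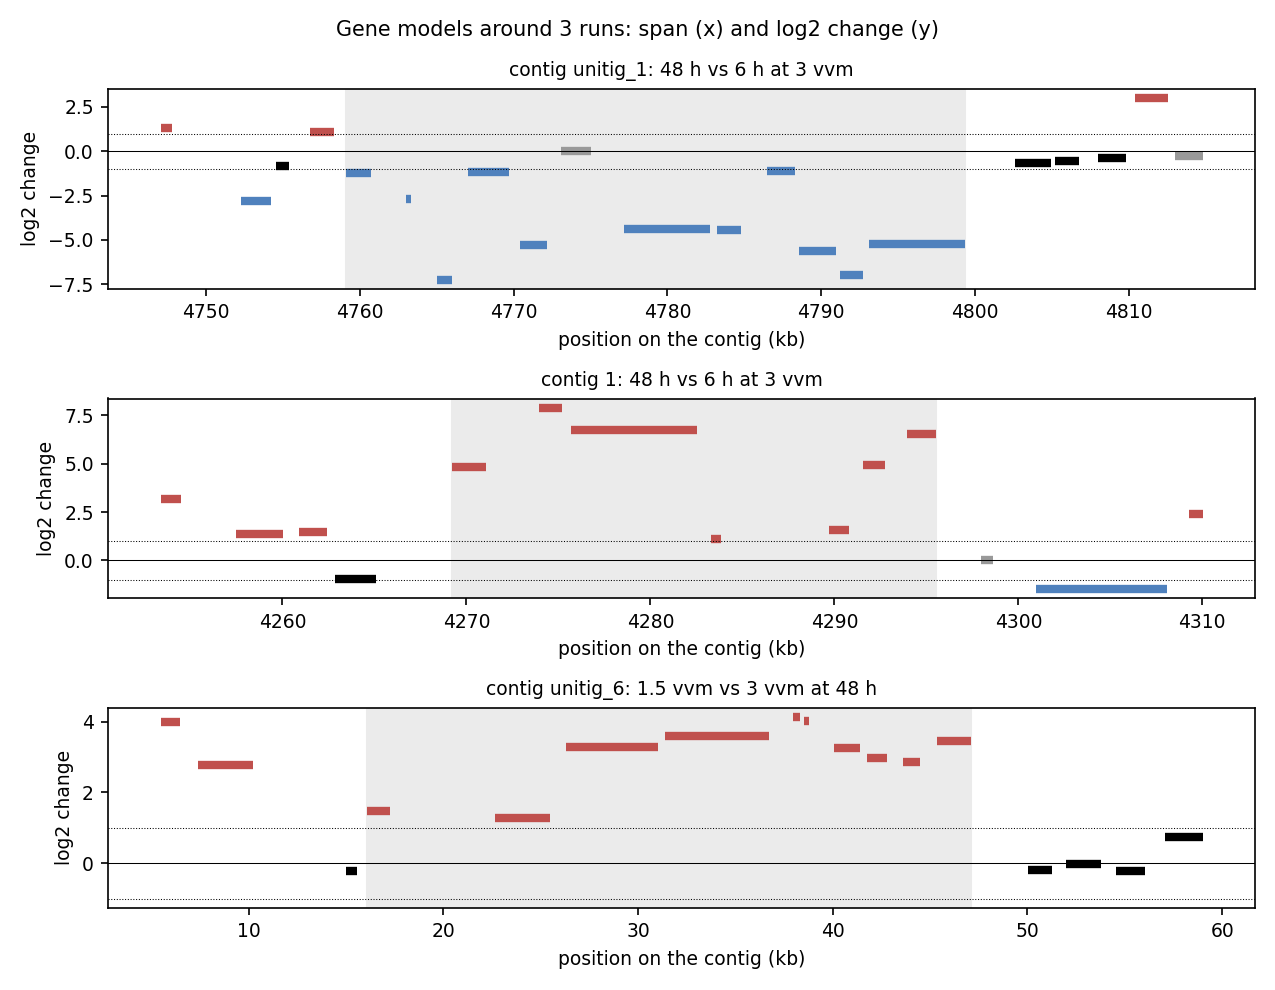
Horizontal bars are gene models, drawn at their span (x axis, kb on the contig) and log2 change (y axis), red when at least 2-fold higher, blue when at least 2-fold lower, black when between, and grey when below 1 FPKM in both libraries. Shading marks the runs of 11 genes on unitig_1 and of 7 genes on contig 1 (48 h relative to 6 h) and of 10 genes on unitig_6 (1.5 relative to 3 vvm).

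Near contig ends, 43.2% of 407 genes were higher at 1.5 vvm (38.4 to 48.2), against 21.2% of 9362 genes elsewhere (20.4 to 22.0). Among genes of at least 10 FPKM the shares were 32.3% and 15.4%, and with the median of the silent genes taken off they were 27.8% and 15.5% of all genes kept. Lower at 1.5 vvm were 2.70% of the genes near ends and 2.83% elsewhere. With that median taken off, which lowers low genes most, these were 10.6% and 5.33%. Genes near ends had a lower level, with a median of 6.58 FPKM in the higher library against 33.9 elsewhere. Among all genes of 1 to 10 FPKM, 978 of 2252 were higher and 24 lower. The shares were not matched on level, so level and position cannot be told apart here.

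Genes that differed over time at 3 vvm passed 2-fold the other way at 1.5 vvm more often than other genes of the same level. Of 1012 genes at least 2-fold lower at 36 h than at 6 h, 457 (45.2%) were at least 2-fold higher at 1.5 than at 3 vvm at 48 h, where independent lists would share 177 and other genes of the same level at 48 h and 3 vvm would give 271. With the median of the silent genes taken off, 358 of 951 genes were higher, where genes of the same level would give 176. Of 1564 genes higher at 36 h, 174 were lower at 1.5 vvm, where independent lists would share 47.9 and genes of the same level would give 23.9. Another 223 were higher, where these would be 274 and 244. These 2 comparisons have no library in common, and the counts matched on level were added after the data were seen. Groups by time of highest value, chosen on the libraries at 3 vvm, went from their median at 48 h and 3 vvm to that at 1.5 vvm as follows: highest at 6 h, 5.19 and 15.3 FPKM; at 12 h, 10.5 and 26.8; at 24 h, 30.5 and 46.0; at 36 h, 32.9 and 30.2 FPKM. Genes highest at 48 h had 44.7 and 30.9 FPKM. All these groups were chosen in part on the 48 h library at 3 vvm, through the 4-fold range. Part of these differences can therefore come from the choice. In the runs that were lower over time, 9 of 10 genes on contig 1 from 3043016 were listed with the 1.5 vvm library. Their median was 36.4 FPKM there, against 18.9 at 48 h and 3 vvm. The 11 genes on unitig_1 from 4759122 had medians of 12.5 and 6.62 FPKM. These runs were chosen as low in that 48 h library, so part of these differences can come from the choice.

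**Figure D5:**
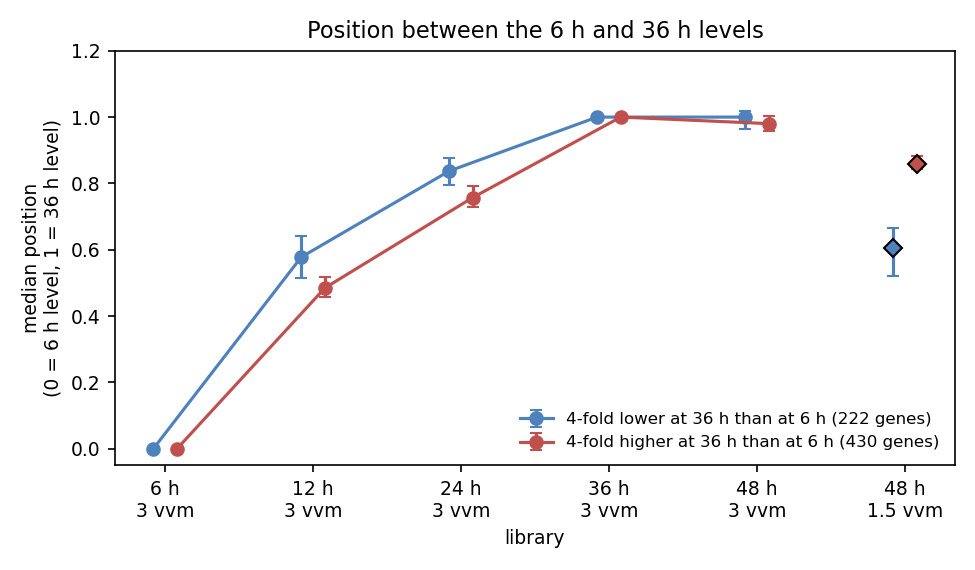
For 222 genes at least 4-fold lower (blue) and 430 at least 4-fold higher (red) at 36 h than at 6 h, points give the median position of each library between the 6 h level (0) and the 36 h level (1) on the log2 scale, with 95% intervals from resampling genes. At 1.5 vvm (diamonds) the medians were 0.60 for the lower and 0.86 for the higher genes, and at 48 h and 3 vvm 1.00 and 0.98.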

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

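All tests of this part were chosen after the data were seen, and for 3 of them the deciding values had not yet been computed: the thinning, and both uses of the floor on genes of higher level. Both uses of the floor had an outcome nearly fixed by the floor's size.

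A signal appeared in genes that no comparison used. The table with the 1.5 vvm library listed 304 genes that the time course table did not, and all were at 0 in the 24 h library beside them. Being listed there required a fragment at 1.5 vvm. They had a median of 1.92 FPKM and 5 fragments, and 94 had only 1 or 2. Above the 3 fragments that a count of 0 allows were 181 genes, and 21 were at 10 FPKM or more. Taken as 0 at 3 vvm, they brought the genes higher at 1.5 vvm to 2400.

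Almost no gene was silent at 1.5 vvm: of genes below 0.5 FPKM in all 5 libraries at 3 vvm, 2 of 444 were at 0 there (unlisted genes counted as 0), while of genes below it in 4 libraries at 3 vvm, 37.6% to 52.6% were at 0 in the fifth. Greater depth was argued against, since thinning the 1.5 vvm library to the fragments of the 6 h library left 24 genes of both tables at 0 (17 to 32 in 20 draws), against 448 at 6 h, or 47 against 462 with the 23 unlisted genes. With a floor of equal density and counting error alone, 95.5% of the 442 such genes in both tables would lie within 2-fold of their median FPKM. Only 71.9% did (67.5 to 76.1), so these values spread more than such a floor alone would give. The share lay between the bounds set for either outcome, and a floor as a part of these values stays open. Lower aeration, DNA carried into the library, another library preparation and any other property of this 1 library cannot be told apart here and were not tested one by one, which leaves open what the low values at 1.5 vvm measure, among them those of 978 of the 2167 higher genes, at 1 to 10 FPKM.

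Among genes of at least 50 FPKM, more were higher than lower at 1.5 vvm (424 and 150, or 73.9% higher). With 1.57 FPKM taken off, 71.5% were higher (67.6 to 75.1). An equal floor of this size is too small to make the split at this level. That outcome was nearly fixed beforehand by the size of the floor, so it adds no evidence. A floor that differs between genes was not tested, and the silent genes ran from 0.739 to 4.25 FPKM (percentiles 10 and 90). Scaling between the libraries as the whole cause was argued against for median-ratio scaling on these genes only, after which 68.1% were higher (64.0 to 72.0). A common sum, which moved the split of all genes more, was not tried on them. What remains may be a response to the lower air supply or a difference between the 2 cultures or libraries, which 1 library per rate leaves open.

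Genes that were lower at 36 h than at 6 h stood closer to their 6 h level at 1.5 vvm. Their median position was 0.60 from 6 h (0) to 36 h (1), against 1.00 at 48 h and 3 vvm. With the floor of 1.57 FPKM taken off, the position was 0.65 (0.57 to 0.74). These genes had a median of 22.4 FPKM at 1.5 vvm and 9.44 at 48 h and 3 vvm. An equal floor of this size is too small to make that difference, so the outcome was nearly fixed beforehand and adds no evidence. A floor that differs between genes was not tested. On an earlier point of the same course, genes that were higher at 36 h would be no further along than the lower ones. At 12 and 24 h they lay behind, by differences of -0.09 and -0.08. At 1.5 vvm they lay 0.25 further along (0.19 to 0.34), or 0.19 (0.103 to 0.275) with the floor taken off. That goes against an earlier point but does not settle it. The bound set was 0.10, and the intervals resample genes that are not independent, so they are too narrow. A scale difference between libraries would move the 2 sets apart in the same way, and another scaling was not tried here. RNA with the profile of the 6 h library at 1 share was argued against as the whole cause: of 113 such genes of at least 100 FPKM at 6 h, 26.5% (18.7 to 35.7) implied a share within 2-fold of the median of 9.09%, against 51.3% to 78.8% in 6 mixtures computed from libraries at 3 vvm, though the bounds were set with the range of shares known (percentiles 10 and 90 at -4.22% and 83.3%). RNA with that profile brings each gene at least its share of the 6 h level. Yet 14 of the 113 genes (12.4%, 6.94 to 19.9) were under 0.5 of the level that the median share would bring. The mixtures held 0 such genes, which was fixed by how they were made and adds no evidence. The 14 genes lay below what that share would bring. Yet the 12.4% lay between the bounds set for either outcome, so the test could not decide on such RNA as a part. A part played by that share or a smaller one, or by mycelium with a profile only near that of 6 h, stays open. The lowest of these genes, evm.model.unitig_5.1067, was at 0.145% of its 6 h level. A response to the lower air supply also stays open, as untested, since 1.5 vvm has 1 library and none before 48 h.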

How the results depend on the processing

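Alternatives named as added were chosen after the data were seen; the others were fixed before. Of 122 alternative values of the 2-fold counts, 86 stayed within 1.5 times, among them those with a pseudocount of 0.1 FPKM, no filter and median-ratio scaling, and, added, with the counting interval, depth-scaled fragments and thinning. The 10 values without a filter could not move, since 2 values under 1 FPKM are never 2-fold apart on the log2(FPKM + 1) scale. At a 4-fold threshold 164 genes were higher and 148 lower at 12 h, 322 and 215 at 24 h, 503 and 276 at 36 h, 558 and 267 at 48 h, and 568 and 51 at 1.5 vvm. At 1.5-fold these were 1424 and 1465, 2021 and 1701, 2626 and 1931, 2485 and 2024, and 3514 and 716. The threshold's own construction moved these. With a pseudocount of 5 FPKM, 404 genes were higher and 379 lower at 12 h, 529 were lower at 24 h, 659 at 36 h and 696 at 48 h, and 1067 were higher at 1.5 vvm, since low genes move less on that scale. With 12 h as the base, 479 and 375 genes were higher and lower at 24 h, 828 and 421 at 36 h, and 1032 and 482 at 48 h. For 1.5 vvm, a filter of 10 FPKM left 1189 higher, rescaling to a common sum gave 465 lower, the added removal of the floor 512 lower, and the added 24 h base 147 lower. The cause was not tested for these. Genes with a 4-fold range highest at 6, 12, 24, 36 and 48 h numbered 188, 48, 80, 144 and 209 with a pseudocount of 5 FPKM, and 150, 84, 128 and 231 from 12 h on without the 6 h library. Added neighbour correlations at 48 h were 0.206 with a pseudocount of 5 FPKM and 0.194 with a filter of 10 FPKM, and at 1.5 vvm 0.153 and 0.140. In the added edgeR trend, time in hours gave 258 rising and 175 falling genes, and leaving out 1 library gave 209 and 106 without 6 h, 219 and 168 without 36 h, 302 and 301 without 48 h, and 803 to 829 rising and 738 to 832 falling without 12 or 24 h. No named gene or neighbour correlation changed sign, though named changes of this size could hardly do so. Counts were not scored for direction, and small balances did change side. At 12 h, 681 genes were higher and 631 lower at 2-fold, but 1424 and 1465 at 1.5-fold. In the edgeR trend 855 rose and 854 fell, but 803 and 832 without 12 h. Of the named genes, 18 of 24 values stayed within their counting interval. The other 8 values, of both named genes at 0 in one library, have an interval with no upper limit and say nothing on stability: their log2 change was 6.87 to 12.5 and 4.92 to 10.5. Alternatives on deposited confidence intervals, on gene lists and on a second copy of the 48 h library were not run, since the files hold no intervals, names or second copy. With 1 library per group none could be left out within a group. Depth limits genes of few fragments: counting error alone put 108 to 179 genes past 2-fold.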

Other observations

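The tests of this part were chosen after the data were seen. The edgeR model with log2 time and aeration over all 6 libraries gave 710 genes higher and 174 lower at 1.5 vvm, of 9485 genes, at a Benjamini-Hochberg adjusted p below 0.05. Its aeration term fits the 1 library at 1.5 vvm exactly, so the p-values rest on how far the libraries at 3 vvm lay from a line, and the library at 1.5 vvm is assumed to vary like them. These counts therefore describe 1 library and do not test aeration.

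Of the runs that were higher at 48 h than at 6 h, the 7 genes on contig 1 from 4269213 had a median of 333 FPKM at 1.5 vvm and 243 at 48 h and 3 vvm, and the 8 genes on contig 1 from 4186899 had 104 and 94.6. The 6 genes on unitig_3 from 3527403 to 3538679 had 65.8 and 92.4 FPKM, and 3.10 at 6 h. A run of the aeration comparison, the 6 genes on unitig_6 from 1925978 to 1942836, had a median of 36.0 FPKM at 6 h, 17.8 to 19.3 at the later times at 3 vvm, and 133 at 1.5 vvm. These runs of 6 genes were picked after their values were seen. All runs given here were also chosen on the 48 h library at 3 vvm, which enters these comparisons.

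The gene evm.model.unitig_2.1242 was at 0 at 6 and 12 h, 353 FPKM at 24 h, 53.1 at 36 h, 582 at 48 h and 4141 FPKM (2239 fragments) at 1.5 vvm.

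Chance order of the times was tested as an explanation of the edgeR trend. The real order gave 1709 genes, and 1 of 100 orders, the real one, gave as many. The highest of the 99 other orders drawn gave 1422, and it exchanged only the 36 and 48 h libraries. Chance order was therefore argued against among the orders drawn, but not excluded. A share of 1 in 100 is the smallest that this test can give, and not every possible order was drawn. Anything else that changed in step with time would give the same count.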
